A study of Mus musculus with 6 samples.

How the data were processed

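Each of the 6 arrays held biotin-labelled cRNA made from the total RNA of 1 mouse's tumour cells, 3 WT and 3 EKO, with an Affymetrix 3' IVT kit, per the labels' protocols. The groups and replicate numbers were taken from the sample titles, which call the replicates biological. The design text and the sample protocols name different RNA extraction kits, and which one was used is not settled by the sources used here. The authors deposited log2 values made with RMA and Partek 6.6, per the submitters' processing notes. RMA corrects the background, normalizes quantiles between arrays and summarises the probes of each probe set, which pulls the arrays' distributions together and narrows differences near the floor. The values ran from about 2 to 15 with nearly equal quantiles in every array, and were used as deposited. Scan dates and slide batches are not given in the sources used here, so no batch was tested.

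Of 45101 probe sets, 64 were controls and were left out. Of the others, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were unnamed here. The annotation's Entrez identifiers matched a RefSeq gene table of the mouse for 34741 probe sets, and 0 symbols changed. Probe sets with several symbols or none were not used for genes. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays, a rule that mattered for 9010 genes with several probe sets. No filter on low values was set because the values carry no detection calls. No coordinates are given, since a genome build for the array is not given in the sources used here.

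EKO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The difference is always EKO minus WT on the log2 scale. Gene lists, 31 with 708 genes of which 647 were measured, were written from general knowledge before the data were examined, as were the design, the naming rule and all alternatives except 1. Of the lists, 19 describe programmes of skin and tumours and 12 describe markers of other cell types or of dissociation stress, some genes standing in more than 1 list. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists, and members were also adjusted over the list alone. The score of a list in an array is the mean over its members of the difference from the mean of the 6 arrays.

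Named genes were Fabp5, the other measured Fabp genes and Sox2. To these were added up to 12 genes per direction past the threshold with no overlap between the groups, ranked by size, filled where fewer passed with the smallest unadjusted p among genes with a log2 difference of at least 1 in size and no overlap, skipping predicted genes and unnamed loci. The rule also took up to 4 members of each list by smallest unadjusted p. Other genes were chosen after their values were seen and are named as such or stand in plots. The alternatives were a replicate block, only genes in the upper 50% of means, a repeated quantile normalization, centred array medians, an intensity trend with robust variances, array weights, a mean over a gene's probe sets, each array left out in turn, all probe sets, a minimum log2 difference of 1 and a threshold of 0.1. The list of fatty acid binding and uptake without Fabp5 was added after seeing the data.

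The procedure was tested on simulated data with the means and spreads of the 18193 genes and 200 changed genes, in 20 simulations. It recovered 92.2%, 99% and 99.8% of genes changed by 1, 2 and 4 on the log2 scale, with 5.83% of calls false, and called 0.15 genes on average in unchanged data. A list shifted by 0.5 was found in 20 of 20 simulations. The simulated genes varied independently, so these shares do not cover the correlation between genes of real tumours. Each shift was the same in all EKO arrays, so the shares do not cover changes that differ among EKO tumours either. The real genes had a median residual SD of 0.14, and the number of arrays, 3 per group, limits the precision.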

Results

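Gene expression was measured on Affymetrix 3' arrays in cells from mouse skin tumours. Wild-type (WT) mice and mice deficient in the epidermal fatty acid binding protein E-FABP (EKO), a carrier of fatty acids encoded by Fabp5, had been treated for 5 months with DMBA, a carcinogen that starts skin tumours, and TPA, a phorbol ester that promotes their growth. Tumours were digested to single cells, and total RNA was taken from the tumour cells of 3 mice per group. The sample labels call the cells keratinocytes, while the design text calls them tumour cells, so other cell types of the digested tumour were followed with marker lists. The 6 arrays had nearly equal medians, from 5.41 to 5.43 on the log2 scale, and each pair correlated across probe sets with r between 0.988 and 0.994. The number of arrays limits the precision of every value.

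The comparison of EKO with WT tumours asks which transcripts differ in chemically induced skin tumours that lack E-FABP, and the study's title puts SOX2 in keratinocytes at its centre. Fabp5 itself fell by 6.69 on the log2 scale, from 14.85 ± 0.073 in WT to 8.16 ± 0.166 in EKO tumours (mean ± SD, n = 3 each). The WT values lay close to the highest values of their arrays, 14.91 to 14.96, so the size of this fall is not exact and may be an underestimate. Sox2, a transcription factor of stem and progenitor cells, had a mean of 7.02 in EKO and 3.40 in WT tumours, a log2 difference of 3.63 (SE 0.851), but did not pass the test with all 6 arrays (limma adjusted p = 0.593). Its WT values all lay below the lower quartile of their arrays (3.91 to 3.95), where RMA narrows differences. The data carry no detection calls, so the size of its difference is not exact either. Most listed genes of antigen presentation and of macrophages and dendritic cells had lower means in EKO tumours. Most listed genes of the xenobiotic and oxidative stress response and of the Ras and MAPK output had higher means. These 4 were among 15 lists that passed as sets with a preset correlation between genes, and none passed with an estimated one (smallest adjusted p = 0.465). Markers of other tissue were also among the 15, such as hair follicle genes (median difference 0.88) and skeletal muscle markers (-0.97). Among 18193 genes, Fabp5 alone passed the threshold with all 6 arrays, 1 gene lower and 0 higher.

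By unadjusted p under 0.05, 625 genes were higher and 673 lower in EKO tumours, 1298 in all where chance alone gives 910 on average. How widely the chance count varies with correlated genes was not measured. With 1 array left out the count ran from 838 to 1801. For 2178 genes, 12% of those tested, the 3 EKO values did not overlap the 3 WT values, and chance gives 10% on average. A log2 difference of at least 1 in size with no overlap was seen for 49 genes on the higher side and 24 on the lower side. Leaving out EKO replicate 2 raised the number of genes past the threshold from 1 to 42, of which 38 were higher and 4 lower, and leaving out WT replicate 2 gave 2 genes. With EKO replicate 2 left out, Sox2 was among the 42 (log2 difference 4.72, SE 0.272, adjusted p = 0.00416; range of adjusted p over the alternatives for Sox2, 0.00416 to 0.998).

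Both Fabp5 probe sets on the array separated the groups without overlap. The brighter probe set read 14.82, 14.94 and 14.80 in WT replicates 1, 2 and 3 and 8.21, 8.30 and 7.98 in EKO replicates 1, 2 and 3 (adjusted p = 1.04e-06). The dimmer probe set had a mean of 14.27 in WT and 5.59 in EKO tumours, the latter close to the array medians and not shown to be above background. Fabp5 ranked 2 of 45101 probe sets by its mean in WT tumours with the brighter of these and 69 with the dimmer. Such ranks and percentiles compare signals of probe sets, which differ even within this gene, and do not measure transcript levels. In EKO tumours the brighter probe set still lay at percentile 81 of all probe sets and the dimmer at percentile 52.3, and where each lies relative to the disrupted part of the gene is not given in the sources used here. All 6 arrays matched their labels by this gene. No other measured member of the Fabp family passed: the mean log2 value of Fabp4, the adipocyte fatty acid binding protein, was 13.56 in EKO and 12.86 in WT tumours (difference 0.70, SE 0.412, adjusted p = 0.765), and the differences of Fabp1, Fabp2, Fabp3, Fabp6, Fabp7, Fabp9 and Fabp12 lay between -0.32 for Fabp7 and 0.29 for Fabp2. Fabp1 and Fabp2 lay below the lower quartile in all 6 arrays.

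Sox2 was above all 3 WT values in each EKO tumour, but the EKO tumours differed widely among themselves. Its log2 values were 3.56, 3.71 and 2.91 in WT replicates 1, 2 and 3, and 7.87, 4.84 and 8.36 in EKO replicates 1, 2 and 3, so that the SD was 1.91 in EKO against 0.424 in WT tumours. Several other genes with a higher EKO mean had the same order, EKO replicate 2 lying nearest the WT values. Slpi, a secreted inhibitor of leukocyte proteases, read 13.93, 12.30 and 13.96 in the EKO replicates against a WT mean of 11.13 ± 0.149 (difference 2.27, adjusted p = 0.546). Dsc2, a desmosomal cadherin, had a difference of 1.77 and a mean of 10.71 in EKO tumours, and Klf12 and Nexmif had differences of 1.13 and 1.41. The WT values of Nexmif lay below the lower quartile of their arrays. Without EKO replicate 2, Slpi (2.82, adjusted p = 0.00278), Dsc2 (2.25, adjusted p = 0.0143), Klf12 (1.37, adjusted p = 0.0419) and Nexmif (1.82, adjusted p = 0.0148) all passed. With all 6 arrays none of these did, and under other alternatives the adjusted p of each reached 0.998.

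The genes fixed by rule on the higher side were filled by size and non-overlap, since none passed the threshold. They held the collagens Col11a1 (5.36 ± 0.417 in WT, 6.94 ± 0.312 in EKO, difference 1.58) and Col12a1 (difference 1.13), the cornified envelope gene Lce1m (1.14), the keratin Krt77 (1.77), the protease inhibitor family member Wfdc21 (2.44) and the glutathione peroxidase Gpx2 (2.22). The glutathione transferase Gsto1 was 2.84-fold higher by its means. Col11a1 and Wfdc21 varied little among the EKO tumours, with SDs of 0.312 and 0.345, while Gpx2 had an SD of 1.06. The adjusted p of these 7 genes lay between 0.523 and 0.608. Krt77 was highest in EKO replicate 2, at 10.59, against 9.35 and 9.29 in EKO replicates 1 and 3, and it passed when that array was left out (difference 1.34, adjusted p = 0.0107, with up to 0.998 under other alternatives).

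Of the genes fixed by rule on the lower side, apart from Fabp5, Cd209e and Mgl2, lectin genes of macrophages and dendritic cells, had the smallest unadjusted p. Rgs4 and Coch had the largest differences. Cd209e had a mean of 6.13 ± 0.367 in WT and 4.40 ± 0.168 in EKO tumours (difference -1.73, SE 0.19, adjusted p = 0.218), and Mgl2 read 7.57 ± 0.169 and 6.49 ± 0.191 (difference -1.08, SE 0.133, adjusted p = 0.284). The chemokines Ccl8 and Ccl11 had differences of -1.44 and -1.40, and Ear3, of the eosinophil-associated ribonuclease family, had one of -1.01. Rgs4, a regulator of G protein signalling, had a difference of -1.90, the anion transporter Slc26a7 -1.37, the extracellular matrix protein gene Coch -1.87, the cytochrome P450 gene Cyp2g1 -1.66, the protease inhibitor Serpina3n -1.13 and the keratin Krt24 -1.08. The rule took only genes without overlap, so it fixed that all 11 were lower in each EKO tumour than in each WT tumour. None of the 11 passed with all 6 arrays (adjusted p from 0.218 to 0.546). Without EKO replicate 2 Coch passed (-2.23, adjusted p = 0.0162), and without WT replicate 2 Serpina3n passed (-1.41, adjusted p = 0.0476), with up to 0.998 for each under other alternatives.

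**Figure D1:**
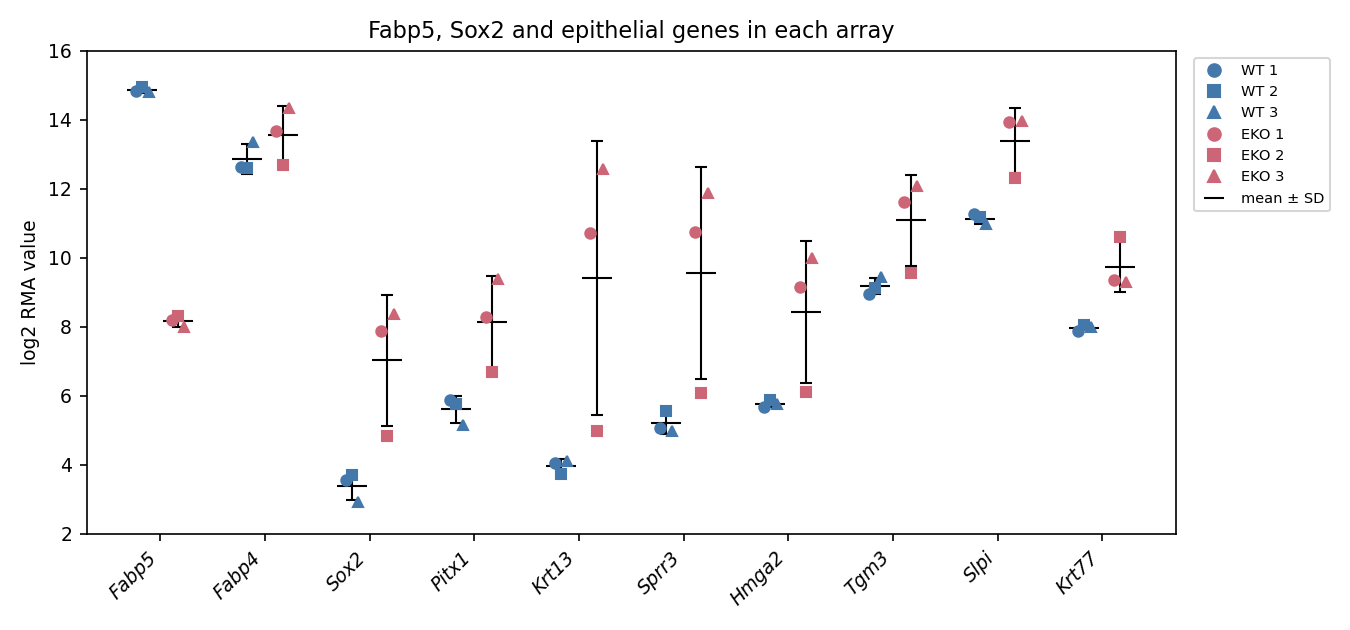
Log2 RMA value (y axis) of 10 genes (x axis) in each of the 6 arrays, with points for WT (blue) and EKO (red) replicates 1 to 3 and black bars for the group mean ± SD. Fabp5 falls from a mean of 14.85 to one of 8.16, while Sox2, Hmga2 and the genes Krt13 and Sprr3, which like Tgm3 were chosen after their values were seen, are high in EKO replicates 1 and 3 and lower in EKO replicate 2, whose values still lie above all 3 WT values.

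Gene lists fixed in advance were tested as sets with camera, which compares a list's genes with all others. With the preset correlation of 0.01 between genes, 15 of 31 lists passed, 6 higher and 9 lower in EKO tumours. With a correlation estimated from the data 0 passed, and the smallest adjusted p was 0.465. Splits of the 6 arrays that mix the genotypes also passed from 5 to 15 lists with the preset correlation. A pass with it therefore does not by itself mark a difference between EKO and WT tumours. Fry, which asks whether a list's genes move on balance one way, passed 1 list, fatty acid binding and uptake, and its test for movement in either direction passed that list and the B and plasma cell markers. Apart from Fabp5, no member of any list passed over all genes, and the counts of members given for each list are those adjusted over the list alone.

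Of the keratinocyte lists, the basal list was higher in EKO tumours with the preset correlation and the others did not pass. Terminal differentiation genes had a median log2 difference of 0.07, with 30 of 41 measured members higher by their means (camera adjusted p = 0.0698). Adjusted over the list alone 1 of them, Krt77, was higher and 0 were lower, and the remaining members named by rule were Lce1m (1.14), the protease Klk7 (-0.38) and the keratin Krt80 (-0.34). This list passed without WT replicate 2 (adjusted p = 0.00023), without EKO replicate 1 (adjusted p = 0.000477) and without EKO replicate 2 (adjusted p = 0.00501). It also passed after a repeated quantile normalization and with a replicate block (adjusted p = 0.0424 for each), with a range of 0.00023 to 0.877 over its alternatives. Basal keratinocyte genes had a median difference of 0.14 over 17 members, 0 of which passed adjusted over the list alone, with Itga3, an integrin of the basal layer, at 0.39 and Wnt4 at 0.42 (camera adjusted p = 0.0223). For this list adjusted p = 0.736 with an estimated correlation. Its call was also lost without WT replicate 3 (adjusted p = 0.143), EKO replicate 2 (adjusted p = 0.194) or EKO replicate 3 (adjusted p = 0.24), with array weights (adjusted p = 0.0695) and with a mean over probe sets (adjusted p = 0.163), the range being 9.54e-05 to 0.753. The median shrank to 0.03 without EKO replicate 3, and was 0.11 without WT replicate 3 and 0.18 without EKO replicate 2. It was 0.10 with array weights and 0.09 with a mean over probe sets, and ran from 0.03 to 0.20 over the alternatives.

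Wound and hyperproliferation genes went both ways. Adjusted over the list alone 2 of 21 members were higher, Slpi and the antimicrobial peptide gene Defb4 (difference 2.29, SE 0.555), and 0 were lower, with Krt17 at -0.26 and the urokinase receptor Plaur at 0.51. The list's median (-0.12) and camera direction were lower while its mean (0.15) was higher (camera adjusted p = 0.79). The 15 enzymes of epidermal ceramides and barrier lipids had a median of -0.01, a mean of 0.08 and a camera direction towards higher (adjusted p = 0.79), with Alox12b, a lipoxygenase of the skin barrier, at 1.07, and 0 members passed adjusted over the list alone. Stem and progenitor cell genes had a median of 0.02 over 29 members (camera adjusted p = 0.684). Beside Sox2, this list held Pitx1, a homeobox gene with log2 values of 8.29, 6.69 and 9.39 in the EKO replicates against a WT mean of 5.60 (difference 2.52), and Prom1 at -0.44, and 0 members passed adjusted over the list alone. Without EKO replicate 2 Pitx1 passed over all genes (3.24, adjusted p = 0.0458), as did Defb4 (3.00, adjusted p = 0.00558), with up to 0.998 for each under other alternatives. The 35 cell cycle genes had a median of -0.04, with Pcna at -0.24 and Ccne1 at 0.34 (camera adjusted p = 0.256) and 0 past adjusted over the list alone. That list passed as lower without WT replicate 3 (adjusted p = 0.00889) and without EKO replicate 1 (adjusted p = 0.0452), with up to 0.866 under other alternatives.

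Most listed genes of the xenobiotic and oxidative stress response had higher means in EKO tumours. Of 25 measured members 19 were higher by their means, the median difference was 0.37, and adjusted over the list alone 2 were higher and 1 lower. The higher ones were Gpx2, a glutathione peroxidase (8.76 ± 0.453 in WT, 11.0 ± 1.06 in EKO), and Gsta2, a glutathione transferase (difference 1.31), and the lower one was Ahr, the aryl hydrocarbon receptor (difference -0.63, from 10.28 to 9.65). Nqo1, a quinone reductase, had a difference of 1.44. Beside Ahr, the 6 members with lower means held the cytochrome P450 genes Cyp1a1 (-0.75) and Cyp1b1 (-0.56) and Ahrr (-0.20). These were named after their values were seen and did not pass adjusted over the list alone. The higher level of the list therefore does not extend to all its xenobiotic genes. As a set the list was higher (camera adjusted p = 0.000104), with adjusted p = 0.465 with an estimated correlation. Over the alternatives its median ran from 0.16 to 0.49. Its mean score lay 0.54 above the mean of the 6 arrays in EKO replicate 3 and -0.05 from it in EKO replicate 2.

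Ras and MAPK output genes were higher as a set, with 17 of 19 members higher by their means and a median difference of 0.26 (camera adjusted p = 0.000236). For this list adjusted p = 0.613 with an estimated correlation, and 0 members passed adjusted over the list alone. The score of EKO replicate 2, -0.14, lay within the WT range of -0.33 to -0.04, and only EKO replicates 1 and 3 lay above that range. Over the alternatives the median ran from 0.17 to 0.36. Ccnd1, which encodes cyclin D1, had a difference of 0.97 (SE 0.274), Hmga2, a chromatin protein of embryonic and tumour cells, 2.65, Fosl1 0.75 and Spry2 0.42. Hmga2 read 9.16, 6.09 and 10.01 in the EKO replicates against 5.77 ± 0.0938 in WT tumours, and passed without EKO replicate 2 (3.82, adjusted p = 0.00605, with up to 0.998 under other alternatives). Targets of p53 were also higher as a set, 16 of 21 by their means, with a median of 0.13 (camera adjusted p = 0.00235) and adjusted p = 0.465 with an estimated correlation. Over the alternatives the median ran from 0.08 to 0.20. Zmat3 (0.52), Ccng1 (0.64), Aen (0.45) and Plk2 (0.37) had the smallest p of that list, and 0 passed adjusted over the list alone.

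Notch, Wnt and epithelial to mesenchymal transition genes did not pass as sets, and 0 of their members passed adjusted over the list alone. The 22 Notch pathway genes had a median of 0.05 (camera adjusted p = 0.0936), with Notch1 at 0.54 and Notch3 at 0.25, and the list passed without EKO replicate 3 (adjusted p = 0.0347) and with array weights (adjusted p = 0.0494), with up to 0.736 under other alternatives. The 24 Wnt pathway genes had a median of 0.02 (camera adjusted p = 0.256), with Wnt5a at 0.70 and Rnf43 at 0.42, and passed as higher without WT replicate 3 (adjusted p = 0.0155, with up to 0.985 under other alternatives). The 25 genes of epithelial to mesenchymal transition had a median of -0.04, a mean of 0.00011 and a camera direction towards lower (adjusted p = 0.384). Their members went both ways, with Fn1, which encodes fibronectin, at 0.70, the repressor Zeb2 at -0.51 and the matrix protease Mmp2 at -0.61.

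Lists of lipid handling had lower medians in EKO tumours. Fatty acid binding and uptake genes had a median difference of -0.16 over 15 members and passed with camera (adjusted p = 0.00144) and with fry (adjusted p = 0.000226), with adjusted p = 0.465 with an estimated correlation. Fabp5 is a member and the 1 gene of the list that fell, both over all genes and adjusted over the list alone. Without Fabp5, a change of the list made after seeing the data, its median was -0.12 and it did not pass (camera adjusted p = 0.0573). Cd36, a fatty acid translocase, had a difference of -0.94 (SE 0.325) and the transporter Slc27a3 one of -0.51, and neither passed. In both genes the value of EKO replicate 2 lay within the WT range, at 10.02 for Cd36 and 7.59 for Slc27a3.

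Genes of fatty acid synthesis and desaturation had a median of -0.21 over 21 members (camera adjusted p = 0.0248), with Elovl6, an elongase, at -0.81, Acsl5 at -0.45 and the desaturase Fads2 at 0.83. For this list adjusted p = 0.736 with an estimated correlation. The call was also lost without WT replicate 1 (adjusted p = 0.114), WT replicate 3 (adjusted p = 0.0923), EKO replicate 1 (adjusted p = 0.396) or EKO replicate 3 (adjusted p = 0.162), the range over its alternatives being 9.32e-06 to 0.753. The median shrank to -0.05 without EKO replicate 1 and -0.11 without WT replicate 1. It was -0.26 without WT replicate 3, -0.20 without EKO replicate 3 and -0.35 without EKO replicate 2. Cholesterol synthesis genes were lower as a set, 13 of 16 by their means, with a median of -0.13 (camera adjusted p = 0.00359) and adjusted p = 0.736 with an estimated correlation. Msmo1, Sc5d and Sqle, enzymes of that pathway, had differences of -0.45, -0.32 and -0.24, and the call was lost without EKO replicate 1 (adjusted p = 0.143) or EKO replicate 3 (adjusted p = 0.0665), the range being 3.46e-06 to 0.753. The median then shrank to -0.04 and -0.09. The 21 PPAR target and fatty acid oxidation genes had a median of -0.14 and did not pass (camera adjusted p = 0.0704), with Ppard at 0.44 and Pparg at -0.60, 2 nuclear receptors that bind fatty acids. They passed as lower without WT replicate 2 (adjusted p = 0.0035) or EKO replicate 2 (adjusted p = 0.000383), with up to 0.76 under other alternatives. Adjusted over the list alone 0 members of these 3 lists passed. The mean score of EKO replicate 2 lay above the mean of the 6 arrays in all 3, by 0.19 for fatty acid synthesis, 0.11 for cholesterol synthesis and 0.15 for PPAR targets, while EKO replicates 1 and 3 lay below it. Elovl6, Acsl5 and Pparg were each highest in WT replicate 1 and lowest in EKO replicate 1, Elovl6 reading 13.12, 12.57 and 12.63 in the WT replicates and 11.42, 12.52 and 11.95 in the EKO replicates. Adipocyte and sebaceous gland markers, described below, were also lower in EKO tumours, 14 of 15 by their means. This list shares Scd1, Scd3 and Elovl3 with the fatty acid synthesis list and Fabp4 with the fatty acid binding list. Fabp4, at 0.70, was its 1 member with a higher mean, so it does not lower either list.

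Antigen presentation genes had the smallest camera p of the 31 lists, and all 16 measured members had a lower mean in EKO tumours. The median difference was -0.31 (camera adjusted p = 2.97e-11), with adjusted p = 0.465 with an estimated correlation. Over the alternatives it ran from -0.38 to -0.25. Adjusted over the list alone 6 members were lower and 0 higher. These were the immunoproteasome subunits Psmb9 (-0.74, SE 0.145) and Psmb8 (-0.81, SE 0.159), B2m, the light chain of class I molecules (13.48 ± 0.0535 in WT, 12.88 ± 0.209 in EKO, difference -0.60), the class II gene H2-Eb1 (-0.39), and the class I heavy chain genes H2-K1 (-0.54) and H2-D1 (-0.48), the last 2 named after their values were seen. Type I interferon response genes had a median of -0.16 and were lower in 24 of 31 members by their means (camera adjusted p = 0.0103), with adjusted p = 0.755 with an estimated correlation. Ifi35 had a difference of -0.40, Irf9 -0.31 and the sensor Dhx58 0.25, 0 members passed adjusted over the list alone, and the call was lost without WT replicate 1 (adjusted p = 0.299) or EKO replicate 2 (adjusted p = 0.479), the range being 1.46e-05 to 0.755. The median shrank to -0.07 and -0.09 in these, and both groups' values of Dhx58 lay less than 0.5 above the lower quartile of their arrays or below it.

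Inflammatory cytokines and chemokines did not pass as a set (camera adjusted p = 0.231), the median of 34 members being -0.08 and their mean 0.09 with a camera direction towards lower. Ccl8, a chemokine that draws monocytes, was lower adjusted over the list alone, 1 member lower and 0 higher, from 11.42 ± 0.31 to 9.97 ± 0.441. Csf1, the growth factor of macrophages, had a difference of -0.43 and Ccl3 one of 1.65, with values of 5.98, 4.27 and 7.05 in the EKO replicates. The list passed as lower without WT replicate 3 (adjusted p = 0.0118) and without EKO replicate 3 (adjusted p = 0.048), with up to 0.867 under other alternatives.

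Among the leukocyte lists, monocyte, macrophage and dendritic cell markers were lower as a set, 22 of 24 by their means, with a median of -0.33 (camera adjusted p = 7.63e-07) and adjusted p = 0.465 with an estimated correlation. Over the alternatives the median ran from -0.45 to -0.23. The mannose receptor Mrc1 had a difference of -1.04 (SE 0.237) and the complement genes C1qa, C1qb and C1qc had -0.59, -0.67 and -0.65, and 0 members passed adjusted over the list alone. Other members, named after their values were seen, differed less, such as Csf1r (-0.13), Itgam (-0.09) and Cd68 (-0.03). The 2 members with higher means were Arg1 (0.47) and Cd14 (0.46). The array with the lowest score of this list was EKO replicate 2, at -0.40 from the mean of the 6 arrays, with EKO replicates 1 and 3 at -0.06 and -0.01 and the WT replicates at 0.27, 0.07 and 0.13. T and NK cell markers were lower as a set with a median of -0.19 over 20 members (camera adjusted p = 0.000582), with adjusted p = 0.477 with an estimated correlation. Over the alternatives the median ran from -0.31 to -0.07. Nkg7, Cd247 and Cd3g had differences of -0.27, -0.30 and -0.42, and 0 passed adjusted over the list alone. Of 11 B and plasma cell markers, Jchain, which joins immunoglobulin chains, was higher adjusted over the list alone (0.69, SE 0.124), 1 member higher and 0 lower, and the list did not pass with camera (median 0.06, adjusted p = 0.868). The WT values of Jchain, 3.68, 3.54 and 3.46, lay below the lower quartile of their arrays and the EKO values, 4.05 to 4.45, little above it. Neither group is shown to be above background. Cd22, a receptor of B cells, had a difference of -0.25. The 19 neutrophil and mast cell markers had a median of -0.05 (camera adjusted p = 0.256), with Mmp8 at -0.69 and S100a9, near the array maxima in both groups, at -0.20, 0 members passing adjusted over the list alone, and passed as lower without WT replicate 2 (adjusted p = 0.0243, with up to 0.867 under other alternatives).

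**Figure D2:**
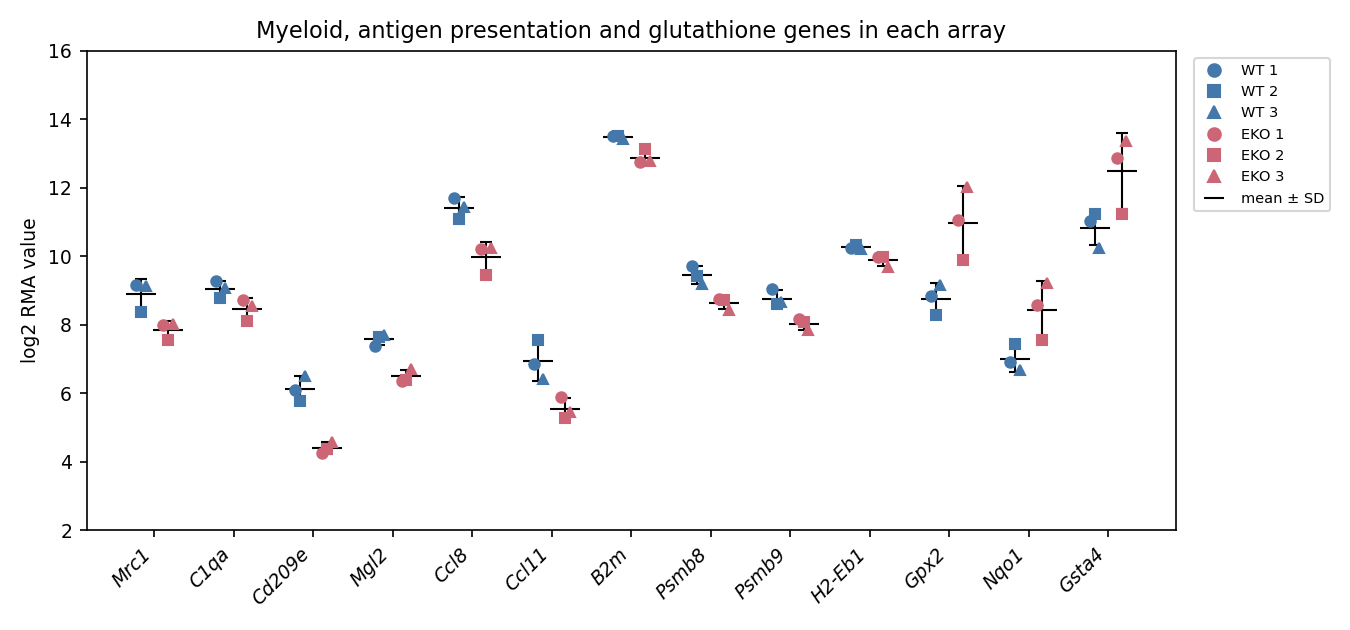
Log2 RMA value (y axis) of 13 genes of macrophages and dendritic cells, chemokines, antigen presentation and glutathione metabolism (x axis) in each array, with points for WT (blue) and EKO (red) replicates 1 to 3 and black bars for the group mean ± SD. Cd209e lies between 5.78 and 6.51 in WT and between 4.24 and 4.58 in EKO arrays, and Gpx2, Nqo1 and Gsta4, the last chosen after its values were seen, spread more among EKO than among WT arrays.

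Markers of other tissue showed that the WT tumours differed from each other. Skeletal muscle markers were lower in EKO tumours as a set with a median of -0.97 over 17 members (camera adjusted p = 0.000504), with adjusted p = 0.736 with an estimated correlation. The score of this list was 2.01 in WT replicate 1 against -0.98 and 0.37 in WT replicates 2 and 3 and -0.91 to 0.12 in EKO tumours, and Mb, which encodes myoglobin, read 10.73 in WT replicate 1 and 7.16 in WT replicate 2. Hair follicle keratin and shaft genes were higher in all 23 members by their means, with a median of 0.88 (camera adjusted p = 8.29e-05) and adjusted p = 0.736 with an estimated correlation. Their score was -1.67, -0.93 and 1.27 in WT replicates 1, 2 and 3 and 0.63, 0.79 and -0.08 in EKO replicates 1, 2 and 3, with the shaft genes Krtap4-16 at 1.21 and Krt32 at 0.92. Adipocyte and sebaceous gland markers were lower as a set with a median of -0.33 over 15 members (camera adjusted p = 0.00758), with adjusted p = 0.736 with an estimated correlation, and Cidea and Far2 had differences of -0.67 and -0.73. In EKO replicate 2 both lay within the WT range, at 11.10 and 11.15, and the list scores of all 3 EKO tumours, -0.30 to -0.01, lay within the WT range of -0.38 to 0.56. All 3 calls were lost without WT replicate 1, with adjusted p = 0.287 for muscle, 0.287 for hair and 0.259 for adipocyte and sebaceous markers. Their medians then shrank to -0.20, 0.29 and -0.19, and over the alternatives they ran from -1.74 to -0.20, from 0.29 to 1.80 and from -0.63 to -0.19. The call of the adipocyte and sebaceous markers was also lost without WT replicate 3 (median -0.30, adjusted p = 0.0731) or EKO replicate 3 (median -0.27, adjusted p = 0.0786). Over the alternatives the adjusted p ran up to 0.753 for all 3 lists, and down to 1.11e-13 for muscle, 2.2e-25 for hair and 6.79e-07 for adipocyte and sebaceous markers. Adjusted over the list alone 0 members of these 3 lists passed.

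Red blood cell markers were higher as a set, with a median of 0.42 over 7 members (camera adjusted p = 0.00207) and adjusted p = 0.465 with an estimated correlation. Over the alternatives the median ran from 0.30 to 0.47. Alas2, the first enzyme of heme synthesis in red cells (0.56, SE 0.126), and Car1, a carbonic anhydrase (0.45, SE 0.103), were higher adjusted over the list alone, 2 higher and 0 lower. The WT values of Car1 lay below the lower quartile of their arrays and the EKO values less than 0.5 above it or below it. Fibroblast and matrix markers had a median of 0.01 over 20 members, 10 higher and 10 lower by their means (camera adjusted p = 0.977), with Dcn, which encodes decorin, at -0.90 and Col5a2 at 0.58. This list passed as lower without WT replicate 2 (median -0.22, adjusted p = 0.0206) and without EKO replicate 1 (median -0.19, adjusted p = 0.0452), with up to 0.994 under other alternatives. Endothelial and mural cell markers had a median of -0.05 over 20 members (camera adjusted p = 0.12), with Cldn5 at -0.68 and Kdr at 0.42, and passed as lower without WT replicate 3 (adjusted p = 0.00506, with up to 0.859 under other alternatives). Melanocyte and Schwann cell markers had a median of 0.12 over 12 members (camera adjusted p = 0.8), with Tyrp1 at 0.51. The 26 genes of dissociation stress and the immediate early response had a median of -0.11 (camera adjusted p = 0.137), with the transcription factors Egr2 at -0.77 and Egr1 at -0.47. They passed as lower without WT replicate 1 (adjusted p = 0.0109), WT replicate 3 (adjusted p = 0.0422) or EKO replicate 2 (adjusted p = 0.0283) and with array weights (adjusted p = 0.0494), with up to 0.76 under other alternatives. Egr2 passed over all genes without EKO replicate 2 (-1.06, adjusted p = 0.0191, with up to 0.998 under other alternatives). Adjusted over the list alone 0 members of these last 4 lists passed.

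**Figure D3:**
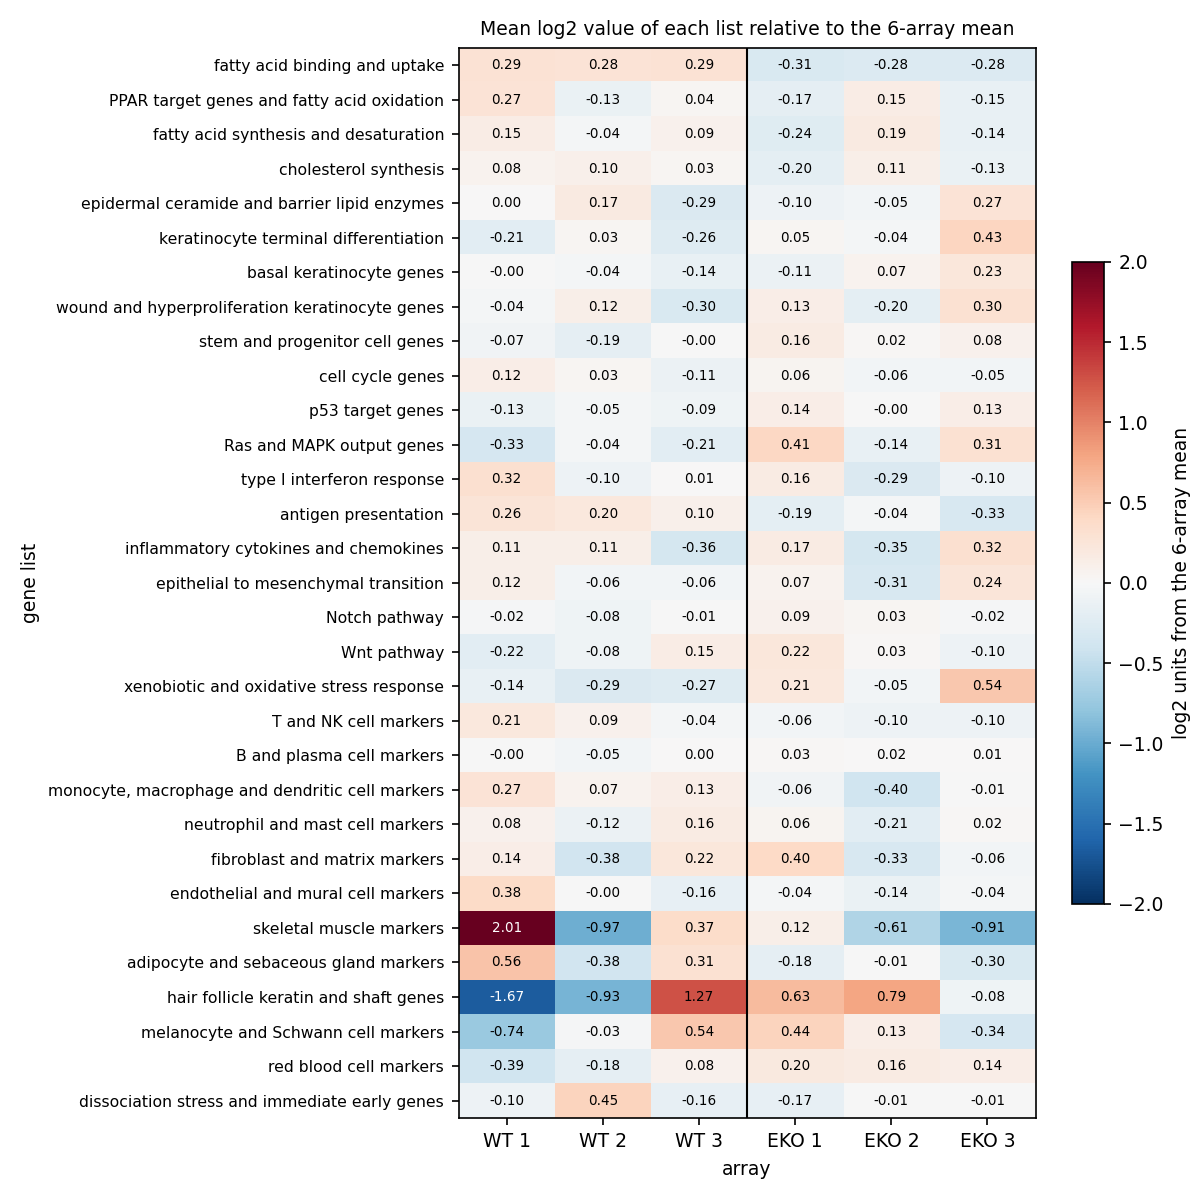
Mean log2 value of each of the 31 gene lists (y axis) in each array (x axis), as the difference from the mean of the 6 arrays, with red above and blue below it and the value printed in each field. Skeletal muscle reaches 2.01 in WT replicate 1, hair follicle genes run from -1.67 in WT replicate 1 to 1.27 in WT replicate 3, and antigen presentation is below 0 in all 3 EKO arrays.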

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

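The fatty acid binding and uptake list without Fabp5, and 13 of the named genes counted below, were chosen after their values were seen. Fabp5 stayed past the threshold under all 13 alternatives run for it, with a log2 difference from -7.69 to -6.60 and an adjusted p from 6.43e-08 to 0.000257. The number of genes past the threshold ranged from 1 to 42 when each array was left out in turn, from 0 to 38 for higher and from 1 to 4 for lower genes, with 2 genes without WT replicate 2 and 42 without EKO replicate 2, and the cause was not settled. It was 2 when all probe sets were tested, since both belong to Fabp5, and 1 at a threshold of 0.1. Sox2 kept its direction in all 12 alternatives that could be run, ranged from 2.96 to 4.72 with 1 array left out and passed only without EKO replicate 2, its SE falling from 0.851 to 0.272. It has no value among genes in the upper 50% of means, where its mean leaves it out. Lists past the threshold numbered 0 with an estimated correlation and 1 by fry, and from 11 to 19 with 1 array left out. The fibroblast and matrix list, with a median of 0.01 and no call, ranged from -0.22 to 0.23 with 1 array left out and became lower without WT replicate 2 (-0.22) and without EKO replicate 1 (-0.19), and the cause was not tested. None of the 146 other genes named by rule passed in the main test, so none had a call to lose. Of 1852 comparisons over these genes, 1841 stayed without a call and 11 gained one, 10 without EKO replicate 2 and 1 without WT replicate 2. The 13 genes chosen after their values were seen gained a call in 10 of 164 comparisons, which is no evidence, since they were picked with their values without EKO replicate 2 in view. Of 464 comparisons over the 31 lists, 394 kept their call or their lack of one, 48 lost a call, 20 gained one and 2 reversed. The sign differed with no call in 6 of the gene and 18 of the list comparisons. The number of arrays limits all of these.

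The replicate numbers did not pair the arrays. Deviations from the group means correlated at -0.0741, -0.0887 and -0.34 for arrays of the same number, and 0 of 3 WT arrays correlated best with their own number. With the replicate number as a block, 1 gene passed, 0 higher and 1 lower, and 16 lists passed, 7 higher and 9 lower, the list that differed being keratinocyte terminal differentiation (adjusted p = 0.0424). Fabp5 stayed at -6.69 and Sox2 at 3.63 under the block.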

Other observations

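Tests of a wrong label, of alleles and leukocytes for antigen presentation, and of hair follicle, melanocyte and neighbouring genes for Sox2 were chosen only after the results were seen, as were the bound that would have ruled out the neighbourhood of Fabp5 and the measures of spread without single genes for the dilution of EKO replicate 2. Leaving out EKO replicate 2, 1 of the alternatives fixed in advance, brought out genes not described above, which were picked singly from the 42 after their values were seen and were not tested as a set. Krt13 and Krt4, paired keratins of mucosal epithelia such as the mouth and oesophagus, were higher without that array by 7.68 (SE 0.501, adjusted p = 0.00651) and 2.80 (adjusted p = 0.0173) on the log2 scale. The WT values of Krt13 lay less than 0.5 above the lower quartile of their arrays or below it, so the size of its difference is not exact. Sprr3, a cornified envelope protein gene active in the same epithelia, was higher by 6.11 (adjusted p = 0.00416), the transglutaminase gene Tgm3 by 2.66 (adjusted p = 0.0107) and Mal, a membrane protein gene, by 3.42 (adjusted p = 0.00414). Krt13 read 10.73, 4.97 and 12.56 in EKO replicates 1, 2 and 3 against 4.06, 3.73 and 4.10 in WT replicates 1, 2 and 3. With all 6 arrays none of these passed, the adjusted p of Krt13 being 0.625, and under other alternatives the adjusted p of each reached 0.998. The terminal differentiation list, which holds Sprr3 and Tgm3, had adjusted p = 0.864 with an estimated correlation when EKO replicate 2 was left out.

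The same 42 genes held Cdkn2a, which encodes cell cycle inhibitors, at 1.44 (adjusted p = 0.0314), and its chromosomal neighbour Mtap at 0.97 (adjusted p = 0.0349). Gclm, a subunit of the enzyme that starts glutathione synthesis, was at 1.46, the activin antagonist Fst at 2.21, the oxidase gene Nox4 at 1.82 and Esm1, an endothelial proteoglycan gene whose WT values lay below the lower quartile of their arrays, at 3.19. On the lower side stood the integrin gene Itgb8 at -0.94. The fit with all 6 arrays reuses the arrays on which the 42 genes were picked, so its signs and unadjusted p are no independent support. Of the 42 genes, 42 had the same sign with all 6 arrays, 38 had an unadjusted p under 0.05 there, and 1, Fabp5, passed there. For 34 of them EKO replicate 2 lay between the WT mean and the mean of the other EKO arrays. Eif2s3y, on the Y chromosome, read from 9.71 to 10.01 in all 6 arrays and Xist from 4.26 to 4.95.

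The first pattern weighed is the larger number of genes past the threshold without EKO replicate 2. Lower array quality, as far as it shows in the normalized values, is argued against as the cause. The interquartile range of relative log expression of EKO replicate 2 was 0.162 against up to 0.178 in other arrays. Its weight of 0.97 was above the lowest, 0.731 in WT replicate 3. Differences in RNA quality that normalization removed, or that touch few genes, would not show in these measures and were not tested. A WT array under a wrong label is argued against by its Fabp5 value of 8.30. Dilution of the cells of the other EKO tumours by 1 common share was tested on the 38 higher genes. Their residual SD, 0.75 or 3.21 times the SD between WT arrays, passed the bound set in advance against dilution. It did so only through Krt13, Krt77, Sprr3 and Ifi209, which held 83.2% of the squared residuals. Without these 4 genes the ratio was 1.39, and by median absolute deviation it was 1.66. Neither measure was part of the prediction. Krt77 was higher in EKO replicate 2, at 10.59, than in EKO replicates 1 and 3, at 9.35 and 9.29. Dilution cannot account for Krt77. The residuals of Krt13, Sprr3 and Ifi209 were -2.8, -1.54 and -1.02, against a WT SD of 0.234 over the 38 genes. These values argue against dilution by 1 common share for these genes. For the rest of the 38, whose residuals did not exceed 1 in size, dilution stays open. The 10 splits of the 5 arrays into 3 and 2 are too few to exclude chance, with 42 genes for the real split, 1 of the 10 reaching that number, and 1 gene for the highest other. A candidate explanation that stays open and untested is that the tumour of EKO replicate 2 differed from the other EKO tumours in stage or type.

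The second pattern is the lower level of antigen presentation genes. Alleles of the major histocompatibility complex that differ between the genotypes could lower the signal of probes inside the complex, but the 5 members coded outside it were also lower, with a median of -0.26, and B2m at -0.60. Only 1 of these 5 had an unadjusted p under 0.05, so alleles cannot be told apart from a change in expression for the members inside. Fewer antigen presenting leukocytes could also lower the list, as macrophage and dendritic cell markers were lower too, but among the EKO arrays replicate 2 had the lowest score of those markers, -0.40, and the highest of antigen presentation, -0.04, and replicate 3 had -0.01 and -0.33. The class I score changed by -0.45 and the class II score by -0.25, a gap of -0.20, yet in EKO replicate 2 the class difference, 0.03, lay among the WT values, so this too stays open.

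The third pattern is Sox2. More hair shaft tissue in EKO tumours as the whole cause is argued against. The list of hair keratin and shaft genes had a median of 0.88 (SD over members 0.20), against a lower 95% bound of 1.62 for Sox2. WT replicate 3 and EKO replicate 2 had the highest hair scores overall and among EKO tumours. Their Sox2 values, 2.91 and 4.84, were the lowest of their groups. The list holds keratin and shaft genes only, so other cells of the hair follicle were not tested and stay open. More melanocytes or Schwann cells are argued against likewise, by a median of 0.12 (SD over members 0.34) and a highest member at 0.53. The highest score of this list was in WT replicate 3. EKO replicate 3, with the highest Sox2 value, 8.36, had a score of -0.34, below those of WT replicates 2 and 3. The list pools both cell types, so these scores do not weigh Schwann cells by themselves. Cell types without a list were not tested and stay open. Sox2 lies on the chromosome of Fabp5 with 84 measured genes between them, and the 37 measured neighbours of Fabp5 had a median size of log2 difference of 0.118, at percentile 86.6 of random sets, which neither shows nor rules out an altered neighbourhood. Sox2 passed only without EKO replicate 2, where it was lower than in the other EKO tumours, as were Krt13, Sprr3 and Hmga2. A tumour stage or type shared by the other EKO tumours but not by EKO replicate 2 was not tested for Sox2. It stays open as a candidate. An effect of E-FABP loss on Sox2, the gene that the study's title puts at its centre, stays open as well.

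The 10 splits of the 6 arrays into 3 and 3 are too few to exclude chance. The real split gave 1 gene, reached by 1 of the 10, and the highest other 0. For the lists it gave 15, reached by 2 of the 10, and the highest other also gave 15. Every other split passed lists too, the lowest giving 5. A pass with the preset correlation therefore does not by itself mark a difference between the genotypes.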
